A study of Homo sapiens and Mus musculus with 24 samples.

How the data were processed

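RNA sequencing of 24 libraries from 2 cell systems was re-analysed. MCF10A is a human mammary epithelial cell line that does not form tumours. Its parental line was compared with a line carrying a heterozygous knock-in of PIK3CA H1047R, an activating change in the catalytic subunit of PI3K alpha; the lines were bought as an isogenic pair. Both lines received the solvent DMSO or the PI3K alpha inhibitor alpelisib (BYL719, dose 1 uM) for 4 h. The mouse embryonic fibroblasts (MEF) received adenovirus carrying GFP, called wild type here, or adenovirus carrying Cre recombinase, which made them homozygous for PIK3CA H1047R. They were treated with DMSO or a PI3K inhibitor at 500 nM, which the series text names GDC0032 and the treatment text GDC500; GDC0032 is used as its name here. The time of that treatment is not given in the sources used here. Each system has 4 groups of 3 libraries. Whether the libraries of a group come from separate clones, infections or cultures is not given in the sources used here. If each genotype is a single line, n = 3 measures the spread of cultures, and clone and genotype cannot be separated in MCF10A. The viral vector and genotype cannot be separated in MEF.

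Reads were paired, 150 nt long for MCF10A and 100 nt for MEF. The authors trimmed them with Trim Galore 0.6.1 and cutadapt and estimated transcript abundance with Salmon 1.2.1, with GRCh38 and GRCm38 as the genome builds, and they also named DESeq2 1.28.1. How RNA was selected and whether libraries were stranded are not given in the sources used here. The deposited tables hold, for every transcript, expected counts (estimated numbers of read pairs, not whole numbers), TPM (transcript abundance that the authors scaled to a fixed sum within each library) and the effective transcript length in nucleotides. Each MCF10A table lists 207749 transcripts with 58434 gene identifiers and 56981 symbols. Each MEF table lists 116248 transcript identifiers without gene names, and the reference used here does not pair those with genes.

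For MCF10A, the deposited expected counts were summed to genes and rounded to whole numbers. For MEF, rounded expected counts of single transcripts were tested, so no MEF gene is named, gene lists were not tested in MEF, and the planned overlap of MCF10A and MEF genes was not run. Reads that several transcripts share were divided by Salmon's estimate. Its bootstrap uncertainty was not used, so the MEF results carry an assignment error that the test does not see. Genes with near-identical copies, such as HSPA1A and HSPA1B, SAA1 and SAA2, histone genes, and KRT14 or KRT16 with their pseudogenes, are uncertain for the same reason, and so are overlapping and antisense genes.

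Totals of estimated pairs were 120177015 to 162755457 per MCF10A library and 42160117 to 52510597 per MEF library. In MCF10A the 20 most abundant genes took 7.83% to 8.92% of each library, and in MEF the 20 most abundant transcripts took 10.3% to 11.5%. Within groups no library was a copy of another: chi-square per degree of freedom between replicates was 4.59 to 167.

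Within each system the 12 libraries were fitted together by group means with edgeR 4.0.16 (quasi-likelihood fit, robust, filterByExpr, TMM scaling, 8 residual degrees of freedom) in R 4.3.3. All tests were two-sided, and genes or transcripts with a Benjamini-Hochberg adjusted p under 0.05 over those tested were called. The 5 comparisons per system were mutant against parental or wild type in DMSO, the inhibitor against DMSO in each genotype, mutant against parental or wild type under the inhibitor, and the interaction, which is the inhibitor effect in mutant cells minus that in parental or wild-type cells. Adjusted p values in the results are from these edgeR tests unless another tool is named. Levels are CPM, which are counts scaled by the TMM library size, with the standard deviation over n = 3 libraries, and log2 fold changes have their standard error (SE).

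The 26 gene lists covered PI3K signalling (FOXO targets, receptor tyrosine kinases and adaptors, PI3K pathway components), metabolism (cholesterol synthesis and uptake, fatty acid synthesis, ATF4 targets, glycolysis and HIF targets, NRF2 targets with the pentose phosphate pathway, lysosome and autophagy genes), growth and stress (MYC and ribosome biogenesis, ERK output, immediate early genes, cell cycle, p53 targets, NF-kB and inflammatory cytokines, interferon response), cell identity (epithelial, luminal mammary and basal mammary markers, mesenchymal regulators, matrix and myofibroblast genes) and markers of other cells (haematopoietic, endothelial, skeletal muscle, adipocyte, and neural and glial). They were tested with limma 3.58.1 camera on voom values (log2 CPM) at a preset correlation of 0.01, adjusted over the lists of each comparison. Lists needed 5 tested members; skeletal muscle markers had 4 and were not tested. Members were also counted after adjustment over the list alone.

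Named genes have the largest changes among called genes with no replicate overlap and a mean of at least 5 CPM in the higher group. Omitted were clone names, predicted genes and symbols ending in P and digits (pseudogenes, but also genes such as MMP2). The rule takes 8 per direction for the mutation in DMSO and the inhibitor in each genotype, 4 for other comparisons and 5 for reversal. It adds PIK3CA and each list's called member with the largest change in each direction. 2 genes that the rule named are not reported here. Other list members were chosen as examples after their values were seen. The comparisons, tests, lists, naming rule and alternatives were fixed before the data were examined, except for added ones identified in the closing section.

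Where 2 comparisons share the mutant DMSO libraries, overlaps were set beside the overlap of independent lists and beside 20 simulations without any effect. These redrew all 12 libraries of a system, controls included, gene by gene around the mean of the mutant DMSO libraries. Fisher's exact test was used for overlaps between comparisons without a shared library. The alternatives were another scaling (RLE), another tool (DESeq2 1.42.0), other filters on low counts, offsets for effective length, a fit of the compared groups alone, a replicate block, a test against a 1.5-fold change (glmTreat), leaving out each library in turn, and other tests of gene lists (an estimated correlation, and fry). The edgeR test was also run on simulated data with known changes.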

Results

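RNA levels were measured by paired-end sequencing in 24 libraries. In MCF10A, parental cells and cells with a heterozygous PIK3CA H1047R knock-in were treated with DMSO or BYL719 for 4 h. In MEF, wild-type cells (adenoviral GFP) and homozygous mutant cells (adenoviral Cre) were treated with DMSO or GDC0032. Each of the 4 groups in each system had n = 3 libraries. The MCF10A libraries held 120177015 to 162755457 estimated read pairs, and 21079 genes were tested. The MEF libraries held 42160117 to 52510597 pairs, and 55500 transcripts were tested. In MCF10A the first principal component took 46.2% of the variance. Mutant DMSO replicate 2 stood apart on the second component (14.4% of the variance) at 54.1, while the other mutant DMSO libraries lay at 14.1 and 17.1.

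The targeted gene itself was examined first. PIK3CA (ENSG00000121879.5, GRCh38 chromosome 3, 179148114 to 179240093) encodes the catalytic subunit p110 alpha. Its level was 57.4 ± 2.03 CPM in parental DMSO, 68.3 ± 2.7 in parental BYL719, 40.6 ± 5.36 in mutant DMSO and 71.0 ± 1.83 in mutant BYL719 (SD, n = 3). PIK3CA was lower in mutant than in parental cells in DMSO (log2 -0.50, adjusted p = 0.000376) and rose with BYL719 in mutant cells (log2 0.81, adjusted p = 1.66e-05). In parental cells its change with BYL719 did not pass the test (log2 0.25, adjusted p = 0.173), though it did without mutant DMSO replicate 2 (adjusted p = 0.00071) and when only the parental libraries were fitted. The difference between the lines under BYL719 did not pass either (log2 0.06, adjusted p = 0.691). The allele carried in the RNA was not analysed here.

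The comparison of mutant with parental MCF10A cells in DMSO asks which genes differ between the lines before any inhibitor. DCN, which encodes the matrix proteoglycan decorin, rose from 4.63 ± 0.644 to 54.5 ± 2.83 CPM (log2 3.56, SE 0.104, adjusted p = 2.94e-10). CFB, complement factor B, rose from 1.58 ± 0.101 to 20.6 ± 1.11 CPM (log2 3.70, SE 0.0769, adjusted p = 4.02e-11), and C1S, a complement protease, rose by a log2 of 3.33. IFI44L, an interferon-induced gene, rose by a log2 of 3.98 (SE 0.117, adjusted p = 3.05e-10), and ZEB1, a transcription factor that represses epithelial genes, by 3.19 (SE 0.105, adjusted p = 6.13e-10). PDE3B, a phosphodiesterase that acts in insulin signalling, rose by 3.32, and the acute-phase gene SAA2 by 3.97, which is uncertain because SAA1 is nearly identical. CADM3, an adhesion molecule of neural cells, had 4 counts over the 3 parental DMSO libraries and 4318 over the 3 mutant DMSO libraries (11.0 ± 0.0906 CPM).

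Several genes with clear expression in parental cells were nearly silent in the mutant line. GPAT2, a glycerol-phosphate acyltransferase, was at 28.4 ± 0.479 CPM in parental cells and 0.0349 ± 0.0308 in mutant cells (log2 -9.61), and RYR1, a calcium release channel, was at 13.2 ± 0.633 and 0.0526 CPM. EEF1A2, a translation elongation factor, fell from 29 ± 0.49 to 1.46 ± 0.331 CPM (log2 -4.31, SE 0.125, adjusted p = 2.94e-10). The ketone body enzyme gene BDH1 fell by a log2 of -5.42, and SEMA4A, a semaphorin, by -3.35. ZNF354C, a zinc finger gene, changed by a log2 of -7.64, and NUDT11 by -3.99. By edgeR's quasi-likelihood test 7213 of 21079 genes were called, of which 3579 rose and 3634 fell; 1081 and 1734 of them changed by at least 1.5-fold.

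Epithelial and basal identity genes were lower in the mutant line and inflammatory genes higher. Of 16 epithelial markers, 12 fell and 1 rose: E-cadherin (CDH1, log2 -1.11), the tight junction gene CLDN4 (-2.29) and the epithelial regulators GRHL2 (-1.60) and OVOL1 (-2.20) fell, and the keratin KRT8 rose (0.37). The camera adjusted p was 9.54e-08, with a median log2 of -0.68, and the adjusted p = 0.00783 with an estimated correlation. KRT8 lost its call when only the 2 groups compared were fitted (adjusted p = 0.0529). Of 19 basal mammary markers, 13 fell and 2 rose, among them TP63 (-1.48), the master regulator of basal cells, and KRT14 (2.37), a basal keratin with pseudogene copies. The median was -0.42 (camera adjusted p = 0.000485; adjusted p = 0.227 with an estimated correlation). Of 16 NF-kB and inflammatory cytokine genes, 15 rose, with CXCL8 (2.67), CXCL1 (2.55) and IL1A (1.60) as examples of secreted mediators. Their median was 1.17 (camera adjusted p = 2.03e-10; adjusted p = 0.0669 with an estimated correlation). Of 16 mesenchymal regulators, 8 rose, including ZEB1, ZEB2 (1.41) and VIM (1.34), and 4 fell, including MMP2 (-3.08); the camera adjusted p was 0.00242 with a median of 0.45, and adjusted p = 0.0403 with an estimated correlation.

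Stress and growth groups were higher as well. Of 18 NRF2 and pentose phosphate genes, 15 rose and PIR fell (-0.30), with the haem-degrading enzyme gene HMOX1 (1.89) and the thioredoxin reductase TXNRD1 (0.84) among those that rose (median 0.55, camera adjusted p = 1.03e-10, adjusted p = 0.0383 with an estimated correlation). Of 28 glycolysis and HIF genes, 19 rose and 2 fell, and 22 rose and 2 fell when adjusted over the list alone. The carbonic anhydrase gene CA9 rose by 2.91 and the glucose transporter SLC2A1 fell by 0.27 (median 0.30, camera adjusted p = 7.34e-08, adjusted p = 0.0403 with an estimated correlation). Of 25 MYC and ribosome biogenesis genes, 21 rose, such as RRS1 (0.65) and PPAN (0.57), which act in ribosome assembly (median 0.23, camera adjusted p = 7.34e-08, adjusted p = 0.0671 with an estimated correlation). Of 21 p53 targets, 13 rose and 2 fell, with PLK2 (0.97) and CDKN1A (0.90) up and PERP (-0.79) down (median 0.43, camera adjusted p = 7.58e-05, adjusted p = 0.0295 with an estimated correlation). Of 20 ERK output genes, 13 rose, such as the feedback inhibitor SPRY4 (1.34) and cyclin D1 (CCND1, 0.90), and ETV4 fell (-0.34). Adjusted over the list alone 14 rose and 1 fell (median 0.58, camera adjusted p = 0.000203, adjusted p = 0.425 with an estimated correlation). Of 25 ATF4 targets, 11 rose and 3 fell, with the cystine transporter SLC7A11 up and the amino acid transporter SLC38A2 down (-0.68; median 0.19, camera adjusted p = 0.00305, adjusted p = 0.108 with an estimated correlation).

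Interferon and matrix genes moved both ways. Of 21 interferon response genes, 12 rose and 3 fell, and 13 rose and 4 fell adjusted over the list alone; IFI44 rose (2.94) and the antiviral gene MX1 fell (-0.80; median 0.38, camera adjusted p = 0.00273, adjusted p = 0.0962 with an estimated correlation). Of 21 matrix and myofibroblast genes, 9 rose and 4 fell, with DCN and the collagen crosslinker LOX (1.68) up and the matrix protein SPARC down (-4.42; median 0.34, camera adjusted p = 0.0378, adjusted p = 0.425 with an estimated correlation). The matrix call was lost without mutant DMSO replicate 3 (adjusted p = 0.0745).

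Genes that FOXO transcription factors activate, and receptors upstream of PI3K, were lower in the mutant line. Of 24 FOXO targets, 16 fell and 3 rose: ERBB3, a receptor that recruits PI3K (log2 -1.97, SE 0.0807, adjusted p = 3.97e-09), INSR, the insulin receptor (-1.19), and BCL6, a transcriptional repressor (-1.05), fell, and GADD45A, a stress gene, rose (0.87). Of 18 receptor tyrosine kinases and adaptors, 12 fell and 3 rose, with PDGFRA (-2.13) and FGFR2 (-1.75) among those that fell. The FOXO median was -0.39 (camera adjusted p = 2.18e-05; adjusted p = 0.104 with an estimated correlation) and the receptor median -0.53 (camera adjusted p = 0.000203; adjusted p = 0.288 with an estimated correlation). Of 28 PI3K pathway components, 12 fell and 2 rose, with the PI3K inhibitor PIK3IP1 down (-1.08) and the transcription factor FOXO1 up (0.72; median -0.12, camera adjusted p = 0.0334, adjusted p = 0.613 with an estimated correlation). Measured against the other mutant DMSO libraries, mutant DMSO replicate 2 had lower levels of the PI3K pathway components (median -0.32), fatty acid genes (-0.30), receptors (-0.27), basal markers (-0.19) and FOXO targets (-0.12), and higher levels of NF-kB genes (0.22) and luminal markers (0.24). Without it the PI3K component call was lost (median -0.06, adjusted p = 0.217), as it was without parental DMSO replicate 3 (adjusted p = 0.0507), and fatty acid synthesis passed the test (median 0.13, adjusted p = 0.0115).

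Other groups did not pass the list test between the lines. Cholesterol synthesis and uptake had 6 that rose, such as the regulator INSIG1 (0.40), and 2 that fell of 21 (camera adjusted p = 0.215). Fatty acid synthesis had 3 and 2 of 13 (adjusted p = 0.358), with the desaturase FADS1 up (0.56). Immediate early genes had 9 and 4 of 19 (adjusted p = 0.43), with the transcription factor genes ATF3 up (0.93) and EGR3 down (-1.40); their median was -0.04 and their mean 0.05. The cell cycle genes had 5 and 9 of 32 (adjusted p = 0.544), where CCND1 rose and CCND2, another D-type cyclin, fell (-2.89); adjusted over the list alone 6 rose and 9 fell. Lysosome and autophagy genes had 9 and 3 of 26 (adjusted p = 0.054), with the autophagy receptor gene SQSTM1 up (0.86). The lysosome list passed without parental DMSO replicate 2 (adjusted p = 0.0499), parental DMSO replicate 3 (adjusted p = 0.0302) or mutant DMSO replicate 3 (adjusted p = 0.0359). Luminal markers had 4 and 5 of 14 (adjusted p = 0.686), with the growth factor AREG up (1.76) and ELF3 down (-2.58); their median was 0.06 and their mean -0.11. Without mutant DMSO replicate 2 the median was -0.0088 for immediate early genes and 0.0024 for luminal markers.

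**Figure D1:**
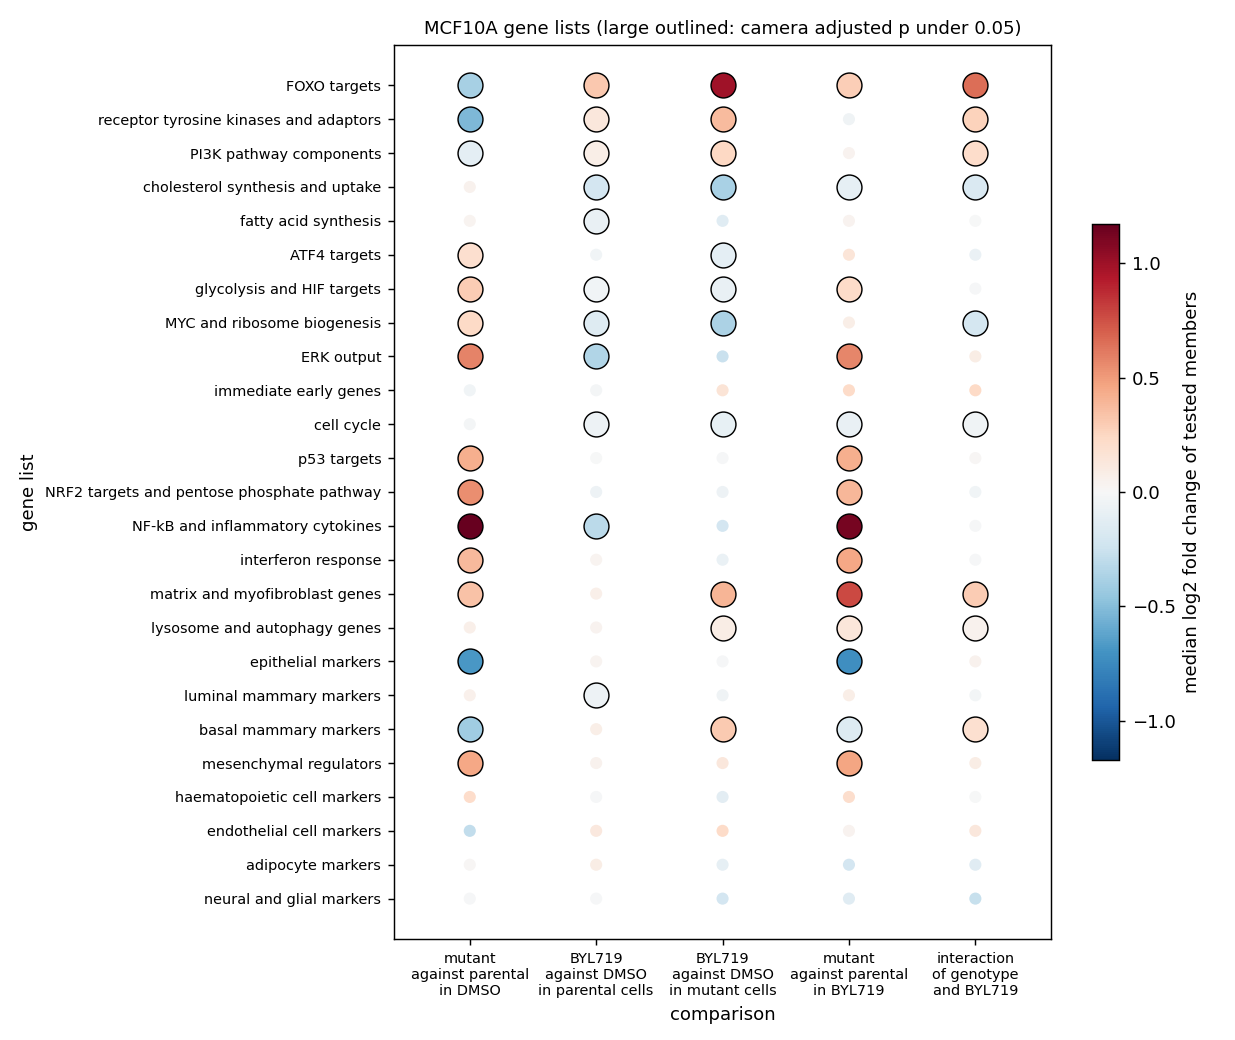
Median log2 fold change of the tested members of 25 gene lists (vertical) in the 5 MCF10A comparisons (horizontal), by colour, red for higher and blue for lower; large outlined symbols have a camera adjusted p under 0.05. FOXO targets are higher with BYL719 in both lines (0.32 and 1.00), and lower in mutant than in parental DMSO cells (-0.39), the latter a call lost with an estimated correlation (adjusted p = 0.104).

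BYL719 against DMSO in parental MCF10A cells shows the response to the inhibitor without the mutation. FOXO targets rose and cholesterol synthesis and uptake genes fell as lists. PDK4 (ENSG00000004799.8, chromosome 7, 95583499 to 95596491), the kinase that slows pyruvate oxidation, rose from 18.9 ± 2.29 to 56.9 ± 2.85 CPM (log2 1.59, SE 0.115, adjusted p = 4.75e-05). DCN rose by a log2 of 1.18, CLDN1, a tight junction gene, by 1.01, BCL6 by 0.84, and GLUL, glutamine synthetase, by 0.83, from 604 ± 22 to 1070 ± 15.5 CPM. HMGCS1 (ENSG00000112972.15, chromosome 5, 43289395 to 43313512), an early enzyme of cholesterol synthesis, fell from 252 ± 4.9 to 137 ± 1.74 CPM (log2 -0.88, SE 0.0527, adjusted p = 1.32e-05), and DMBT1, a secreted mucosal protein, fell by a log2 of -0.80. TCP11L2 rose by 1.02, a call that ended with effective-length offsets (adjusted p = 0.494). BMF, a pro-apoptotic gene, rose by 0.85, a call lost without parental DMSO replicate 1 or 2 or parental BYL719 replicate 2 or 3 (adjusted p = 0.0515 to 0.072). CCND1, which responds to growth factors, fell (-0.63, adjusted p = 0.00634), a call lost without parental DMSO replicate 1 (log2 -0.58, adjusted p = 0.0528) or parental BYL719 replicate 3 (log2 -0.59, adjusted p = 0.0547). FOSL1, of the AP-1 family, fell (-1.0, adjusted p = 0.0404), a call lost without any 1 of the 6 parental libraries (adjusted p = 0.0897 to 0.218) or mutant DMSO replicate 2 (adjusted p = 0.0675), without the low-count filter (0.216) and with effective-length offsets (0.0747).

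By edgeR 302 genes were called in parental cells: 178 rose, 124 fell, and 49 and 11 of them changed by at least 1.5-fold. The spread that the 4 groups share sets this count. It was 1973 without mutant DMSO replicate 2, which is not part of the comparison, with 301 of the 302 kept and more falls than rises (906 rose and 1067 fell), and 3484 when only the parental libraries were fitted. It was 73, 98 and 134 without parental DMSO replicate 1, 2 or 3, and 102, 84 and 78 without parental BYL719 replicate 1, 2 or 3; effective-length offsets gave 134 and DESeq2 891.

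Of the 24 FOXO targets, 10 rose and none fell in parental cells, and 21 rose adjusted over the list alone. PDK4, FBXO32, a ubiquitin ligase subunit of muscle wasting (0.75), and IRS2, an insulin receptor substrate (0.44), were among them (median 0.32, camera adjusted p = 2.87e-25, adjusted p = 0.00479 with an estimated correlation). Of 21 cholesterol genes, 9 fell and none rose, 16 fell adjusted over the list alone, and HMGCS1, INSIG1 (-0.51) and IDI1 (-0.41) led them (median -0.22, camera adjusted p = 2.17e-23, adjusted p = 0.000749 with an estimated correlation). Of 25 MYC and ribosome biogenesis genes, 6 fell, and 12 adjusted over the list alone, with PPAN (-0.43) and NOP2 (-0.32), an rRNA methyltransferase, as examples (median -0.15, camera adjusted p = 4.42e-14, adjusted p = 0.0316 with an estimated correlation).

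Smaller shifts of whole lists passed camera in parental cells and were lost when its correlation was estimated. ERK output had 2 genes that fell (FOSL1, CCND1) and 1 that rose (SPRY2, 0.39) of 20, 5 and 1 adjusted over the list alone (median -0.35, camera adjusted p = 2.61e-05, adjusted p = 0.409 with an estimated correlation). Cell cycle genes had 2 that fell (CCND1 and the replication licensing gene CDC6, -0.19) and 1 that rose (TOP2A, 0.21) of 32, with 4 and 1 adjusted over the list alone (median -0.06, adjusted p = 0.000133 by camera, adjusted p = 0.28 with an estimated correlation). Receptors and adaptors had 3 that rose of 18 (GAB2, ERBB3 and IRS2), and 5 that rose and 1 that fell adjusted over the list alone (median 0.13, camera adjusted p = 0.000133, adjusted p = 0.376 with an estimated correlation). PI3K components had 2 that rose of 28 (PIK3IP1, 0.81, and FOXO4, 0.33), 3 adjusted over the list alone (median 0.08, camera adjusted p = 0.0072, adjusted p = 0.485 with an estimated correlation). The calls of single genes here were fragile. SPRY2 lost its call without parental DMSO replicate 1, 2 or 3 or parental BYL719 replicate 1 or 3 (adjusted p = 0.0501 to 0.0723), and TOP2A without any 1 of the 6 parental libraries (adjusted p = 0.0991 to 0.216), without the low-count filter (0.148), with effective-length offsets (0.245) and with a replicate block (0.0712). GAB2 lost it without parental DMSO replicate 1 or parental BYL719 replicate 2 or 3 (adjusted p = 0.0521 to 0.0717) or with effective-length offsets (0.0697), and PIK3IP1 without parental DMSO replicate 1 or 2 or parental BYL719 replicate 1 or 3 (adjusted p = 0.0533 to 0.0892). Of 13 fatty acid genes edgeR called 0, while 5 fell at an unadjusted p under 0.05, 3 by DESeq2 and 3 adjusted over the list alone (median -0.09, camera adjusted p = 0.00331, adjusted p = 0.409 with an estimated correlation).

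Some further lists were near the limit in parental cells. NF-kB genes had a median of -0.32 (camera adjusted p = 0.0182, adjusted p = 0.409 with an estimated correlation). Of these 16 genes edgeR called 0, while 6 fell and 3 rose at an unadjusted p under 0.05, 3 fell by DESeq2, and 6 fell and 2 rose adjusted over the list alone. The NF-kB list call was lost without parental DMSO replicate 2 (adjusted p = 0.0593) and without mutant DMSO replicate 2 (adjusted p = 0.12). Of 28 glycolysis and HIF genes edgeR called 0, while 4 fell and 1 rose at an unadjusted p under 0.05 and 2 fell by DESeq2; their median was -0.04 (camera adjusted p = 0.0285, adjusted p = 0.409 with an estimated correlation), lost without parental DMSO replicate 3 (adjusted p = 0.0527) or parental BYL719 replicate 3 (adjusted p = 0.127). Of 14 luminal markers edgeR called 0, while 3 fell and 1 rose at an unadjusted p under 0.05 and 1 fell and 1 rose by DESeq2; their median was -0.06 (camera adjusted p = 0.0294, adjusted p = 0.371 with an estimated correlation), lost without the same libraries (adjusted p = 0.0594 and 0.0501). Basal markers (adjusted p = 0.0988) passed without mutant DMSO replicate 2 (adjusted p = 0.02), and NRF2 genes (adjusted p = 0.0889) passed without parental DMSO replicate 1 (adjusted p = 0.0323). ATF4 targets (adjusted p = 0.0988), lysosome genes (0.0988), mesenchymal regulators (0.0803), matrix genes (0.178), p53 targets (0.323; AEN, a p53-induced nuclease gene, fell, -0.50), epithelial markers (0.323), immediate early genes (0.769) and interferon genes (0.855) did not pass.

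BYL719 against DMSO in mutant MCF10A cells asks how the same dose and time act where PI3K alpha carries the activating change. The same directions appeared with larger changes of FOXO targets, and KRT16 and IL1A, which were higher in the mutant line, fell. PDK4 rose from 16.5 ± 1.73 to 184 ± 25.8 CPM (log2 3.48, SE 0.123, adjusted p = 7.2e-09), and PIK3IP1, an inhibitor of PI3K, rose by a log2 of 3.09 (adjusted p = 5.62e-08). CCDC85A (3.60), the hyaluronan synthase HAS2 (2.72), TCP11L2 (2.71), the cationic amino acid transporter SLC7A2 (2.58), the transcription factor BACH2 (2.57) and the transporter ABCA6 (2.37) were among the other largest rises. KRT16, a keratin of stressed epithelia with pseudogene copies, fell from 150 ± 26 to 55.8 ± 2.07 CPM (log2 -1.42, adjusted p = 7.3e-07). HMGCS1 fell by a log2 of -1.32, PHLDA2, an imprinted growth regulator, by -1.35, and the cytokine gene IL1A by -1.08. OSGIN1, an NRF2 target, fell by -1.18, RHOV by -1.14, and HSPA1A, a heat shock gene with a near-identical copy, by -1.27. CSF3, a cytokine, fell by -1.10 (adjusted p = 0.0069), a call lost without mutant DMSO replicate 2 (adjusted p = 0.0632).

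By edgeR 5964 genes were called in mutant cells: 3186 rose and 2778 fell, 1107 and 484 of them by at least 1.5-fold. More fell than rose (46.2% to 49.0% rose) with RLE, DESeq2, no low-count filter or a mean of at least 5 CPM, and without mutant DMSO replicate 1, 2 or 3 or mutant BYL719 replicate 1. With only the mutant libraries fitted, which share no spread with the parental ones, the count was 2610. These counts and the parental ones do not by themselves show a difference between the lines; the interaction tests it.

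Of the 24 FOXO targets, 22 rose in mutant cells, and 23 rose and 1 fell adjusted over the list alone; PDK4, PIK3IP1, DEPP1 (1.79) and ERBB3 (1.78, to 74.7 ± 5.42 CPM) led them (median 1.00, camera adjusted p = 2.78e-21, adjusted p = 0.00857 with an estimated correlation). Of the 21 cholesterol genes, 16 fell, 19 adjusted over the list alone, with HMGCS1, IDI1 (-0.74), INSIG1 (-0.72) and MVD (-0.71) as examples (median -0.38, camera adjusted p = 4.4e-13, adjusted p = 0.00648 with an estimated correlation). Of the 25 MYC and ribosome biogenesis genes, 20 fell, 21 adjusted over the list alone, with RRS1 (-0.99) and PPAN (-0.87) the lowest (median -0.37, camera adjusted p = 2.23e-13, adjusted p = 0.0355 with an estimated correlation). Of 18 receptors and adaptors, 12 rose, such as GAB2, an adaptor that binds PI3K (2.09), and EPHA2 fell (-0.78; median 0.38, camera adjusted p = 2.51e-05, adjusted p = 0.327 with an estimated correlation). Of 28 PI3K components, 14 rose, PIK3CA and the mTORC2 subunit RICTOR (1.02) among them, and the regulatory subunit PIK3R3 fell (-0.52; median 0.25, camera adjusted p = 9.35e-05, adjusted p = 0.468 with an estimated correlation). Without mutant DMSO replicate 2 the FOXO median was 0.81, the receptor median 0.25 and the PI3K component median 0.13, and these lists still passed camera.

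Identity and matrix genes moved in mutant cells too. Of 19 basal markers, 12 rose and 3 fell, 14 and 3 adjusted over the list alone, with TP63 up (1.09) and KRT14 down (-0.33, adjusted p = 0.0704 when only the mutant libraries were fitted). The basal median was 0.30, and 0.19 without mutant DMSO replicate 2 (camera adjusted p = 0.00535, adjusted p = 0.356 with an estimated correlation). Of 21 matrix genes, 10 rose, 13 adjusted over the list alone, such as DCN (1.37) and fibronectin (FN1, 0.55; median 0.40, camera adjusted p = 0.00169, adjusted p = 0.356 with an estimated correlation). Cell cycle genes had 12 that fell and 2 that rose of 32, 14 and 2 adjusted over the list alone, with CCND1 (-0.93) and RRM2 (-0.45), a subunit of ribonucleotide reductase, down (median -0.10, camera adjusted p = 0.00129, adjusted p = 0.313 with an estimated correlation). ATF4 targets had 10 that fell and 4 that rose of 25, 12 and 4 adjusted over the list alone, with TRIB3 (-0.61) down and SLC38A2 (0.87) up (median -0.12, camera adjusted p = 0.0199, adjusted p = 0.313 with an estimated correlation). Glycolysis and HIF genes had 7 that fell, such as EGLN3 (-0.63) and the hexokinase HK2 (-0.62), and 1 that rose of 28 (median -0.08, camera adjusted p = 0.0267, adjusted p = 0.356 with an estimated correlation). The glycolysis list did not pass without mutant DMSO replicate 2 (adjusted p = 0.101). Lysosome genes had 9 that rose of 26, with GABARAPL1 (1.07) the highest (median 0.08, camera adjusted p = 0.0304, adjusted p = 0.356 with an estimated correlation). The lysosome call was lost without mutant DMSO replicate 1 (adjusted p = 0.113), mutant DMSO replicate 3 (adjusted p = 0.212) or mutant BYL719 replicate 1 (adjusted p = 0.0939).

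Several lists with called members did not pass as lists in mutant cells. ERK output had 6 that fell and 2 that rose of 20 (camera adjusted p = 0.0611) and passed without mutant BYL719 replicate 1 (adjusted p = 0.000115). NRF2 genes had 6 and 2 of 18 (adjusted p = 0.0898) and passed without mutant DMSO replicate 3 (adjusted p = 0.0425) or mutant BYL719 replicate 1 (adjusted p = 0.0254). Fatty acid genes had 5 that fell, such as the regulator SREBF1 (-0.39), and 2 that rose of 13 (adjusted p = 0.126), and passed without mutant DMSO replicate 2 (adjusted p = 0.00113). NF-kB genes had 7 that fell, such as IL1A and CXCL2 (-0.78), and 2 that rose of 16 (adjusted p = 0.24), and p53 targets 7 and 6 of 21 (adjusted p = 0.587), with AEN down (-0.79) and TP53INP1 up (0.79). Immediate early genes (5 rose and 3 fell, adjusted p = 0.545), interferon genes (3 and 4, adjusted p = 0.778) and mesenchymal regulators (6 and 1, adjusted p = 0.0898) did not pass. Neither did epithelial markers (5 and 0, adjusted p = 0.52, median -0.02, and 0.06 without mutant DMSO replicate 2, with the test pointing up) or luminal markers (1 and 2, adjusted p = 0.267).

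**Figure D2:**
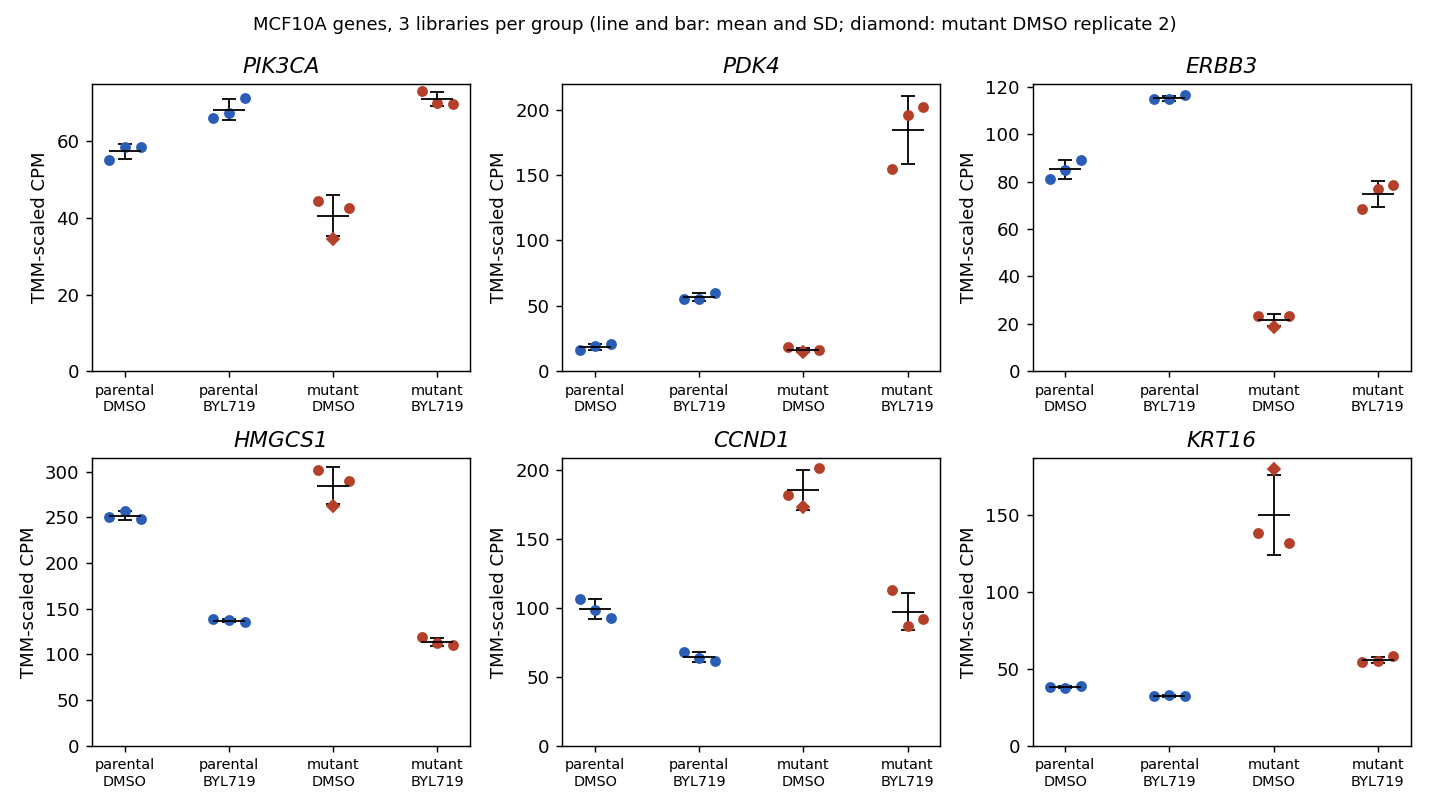
TMM-scaled CPM of 6 MCF10A genes in each of the 4 groups; points are libraries (3 per group), line and bar are the mean and SD, and the diamond is mutant DMSO replicate 2. PDK4 goes from 18.9 to 56.9 CPM with BYL719 in parental cells and from 16.5 to 184 CPM in mutant cells, and KRT16 falls from 150 to 55.8 CPM in mutant cells.

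Mutant against parental MCF10A cells under BYL719 asks which differences between the lines remain with the inhibitor. Loss of epithelial markers and higher inflammatory genes were again seen, while the MYC and ribosome genes did not pass the test. CADM3 (11.6 ± 0.82 CPM in mutant cells), IFI44L (log2 4.01), the prostaglandin receptor PTGFR (4.11) and the phosphodiesterase PDE7B (3.89) were higher, and GPAT2 (-9.53), ZNF354C (-7.87) and RYR1 were lower. Of 16 epithelial markers, 13 fell and 1 rose, 14 and 1 adjusted over the list alone (median -0.73, camera adjusted p = 1.57e-10, adjusted p = 0.0023 with an estimated correlation). Of 16 NF-kB genes, 15 rose, 16 adjusted over the list alone (median 1.12, camera adjusted p = 1.23e-11, adjusted p = 0.0511 with an estimated correlation). FOXO targets lay the other way from DMSO, with 14 that rose and 2 that fell of 24, 15 and 3 adjusted over the list alone. PDK4 (1.69) and DEPP1 (1.04) rose and SESN3 (-1.28), a stress-induced inhibitor of mTORC1, fell (median 0.29, camera adjusted p = 9.2e-05, adjusted p = 0.143 with an estimated correlation). Of the 25 MYC and ribosome biogenesis genes edgeR and DESeq2 called 0, and 4 rose at an unadjusted p under 0.05 (camera adjusted p = 0.103).

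Other stress and identity lists were higher in mutant cells under BYL719 and kept the call with an estimated correlation. Of the p53 targets 15 rose and 3 fell, with a median of 0.43 (camera adjusted p = 3.33e-06; adjusted p = 0.012 with an estimated correlation). NRF2 genes had 15 that rose and 1 that fell, 16 and 1 adjusted over the list alone, with a median of 0.39 (camera adjusted p = 1.14e-11; adjusted p = 0.0224 with an estimated correlation). Mesenchymal regulators had 9 and 2, with a median of 0.47 (camera adjusted p = 0.000165; adjusted p = 0.0224 with an estimated correlation). Glycolysis and HIF genes had 16 and 2, and 22 and 2 adjusted over the list alone, with a median of 0.22 (camera adjusted p = 1.67e-07; adjusted p = 0.0462 with an estimated correlation).

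The remaining calls of lists under BYL719 were lost with an estimated correlation. ERK output rose in 12 genes and fell in 1 (camera adjusted p = 2.37e-06; adjusted p = 0.291 with an estimated correlation). Lysosome genes had 11 that rose and 1 that fell (camera adjusted p = 9.2e-05; adjusted p = 0.0818 with an estimated correlation). Matrix genes had 11 and 3 (camera adjusted p = 0.000101; adjusted p = 0.154 with an estimated correlation), and interferon genes 9 and 2 (camera adjusted p = 0.00319; adjusted p = 0.0987 with an estimated correlation). Cholesterol genes were lower, with 8 that fell and 2 that rose (camera adjusted p = 0.0157; adjusted p = 0.152 with an estimated correlation), as were cell cycle genes with 10 and 3 (camera adjusted p = 0.0129; adjusted p = 0.291 with an estimated correlation). Basal markers had 7 that fell and 2 that rose (camera adjusted p = 0.0245; adjusted p = 0.352 with an estimated correlation), and did not pass without mutant BYL719 replicate 2 (adjusted p = 0.0631). ATF4 targets (adjusted p = 0.102) and immediate early genes (adjusted p = 0.102) passed without mutant BYL719 replicate 3 (adjusted p = 0.044 and 0.0277).

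In this comparison 4709 genes were called, 2411 higher and 2298 lower, a balance that other settings turned round, with 7442 called without mutant DMSO replicate 2 and 4688 of the 4709 kept. Of the genes called in DMSO, 1651 were also higher under BYL719 (409 for independent lists) and 1838 also lower (396 for independent lists), from libraries that the comparisons do not share. Over the 7213 genes called in DMSO the median ratio of the log2 fold change under BYL719 to that in DMSO was 0.62 (quartiles 0.24 and 0.95), and 6304 (87.4%) kept their sign. The ratio was 0.77 over the 2815 genes changed by at least 1.5-fold in DMSO, and 0.49 to 0.67 with 1 library left out. DCN, CFB, ZEB1 and EEF1A2 are examples of genes called the same way with both treatments.

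**Figure D3:**
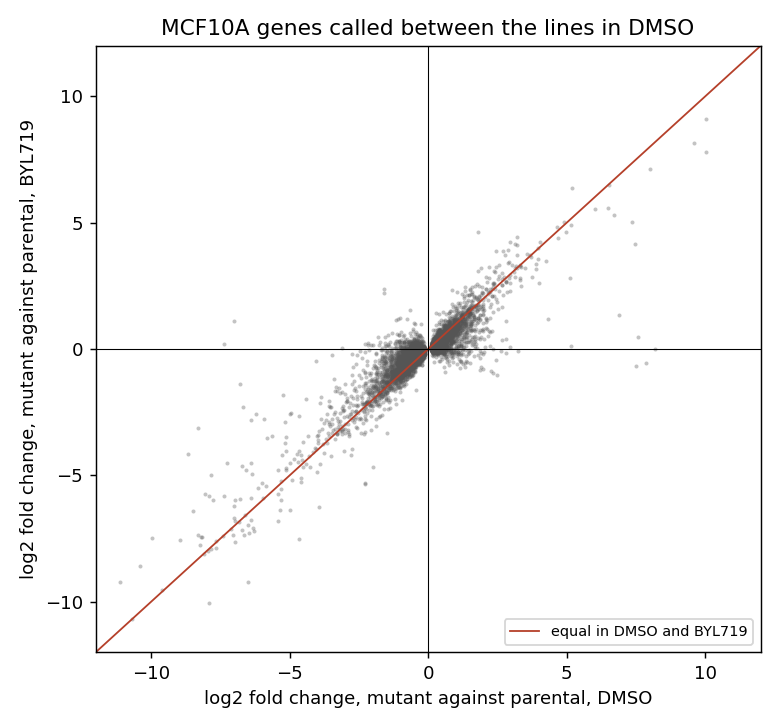
Log2 fold change of mutant against parental MCF10A cells in DMSO (horizontal) and under BYL719 (vertical) for 7213 genes called in DMSO, one point per gene; the diagonal marks equal change. The median ratio of the vertical to the horizontal value is 0.62.

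The reversal comparison asks which differences of the mutant line BYL719 moved back. KRT16, OSGIN1, CSF3, IL1A and the cell cycle inhibitor CDKN1C (log2 1.71, then -1.04) were higher in mutant cells and fell with BYL719. BMF (-1.92, then 2.29), YPEL3 (-1.88, then 2.22), ERBB3, CLDN1 (-1.68, then 1.70) and GLUL (-1.68, then 2.29, from 188 ± 11.9 to 920 ± 86.4 CPM) were lower in mutant cells and rose. Of the 3579 genes higher in mutant cells 1555 fell with BYL719 (472 for independent lists), and of the 3634 lower genes 1611 rose (549 for independent lists), while 200 and 134 moved further in the same direction. Both comparisons use the same 3 mutant DMSO libraries, so opposite changes are favoured by chance. In 20 simulations without any effect 0 to 2 genes were called for the mutation and 0 for BYL719, so their overlap of 0 does not measure this. The covariance of the fold changes was -0.183, and -0.0444 in the simulations (-0.0518 to -0.0351). The correlations were -0.405 and -0.513 (-0.562 to -0.439). The simulations drew each gene independently, so they lack a deviation that many genes share, as in mutant DMSO replicate 2. From the spread of the real mutant DMSO libraries the covariance would be -0.0492. The 3 shared libraries are too few to be divided, so part of the excess over independent lists may come from them.

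The interaction asks whether BYL719 acted differently in the lines. As lists, FOXO targets rose more in mutant cells and cholesterol genes fell more, the latter with 3 of 21 genes called. PDK4 (interaction log2 1.89), PIK3IP1 (2.28), ERBB3 (1.34) and IRS2 were among the 16 FOXO targets of 24 with a more positive effect in mutant cells. Adjusted over the list alone 22 were more positive. The FOXO median was 0.66, and 0.52 without mutant DMSO replicate 2 (camera adjusted p = 2.09e-25; adjusted p = 0.00945 with an estimated correlation). CCDC85A (log2 2.24, adjusted p = 0.000111) and SLC7A2 (2.12, adjusted p = 3.95e-05) responded more in mutant cells, and KRT16 (-1.20, adjusted p = 0.000476) and CDKN1C (-0.97, adjusted p = 0.00438) fell more. SLC7A2 was at 19.2 ± 0.594 and 26.5 ± 2.4 CPM in parental DMSO and BYL719, and at 22.9 ± 4.4 and 137 ± 2.84 CPM in mutant cells. PIK3CA itself had an interaction log2 of 0.56 (adjusted p = 0.0198), lost with effective-length offsets (adjusted p = 0.0828). It was also lost without parental DMSO replicate 2 or 3, parental BYL719 replicate 1 or 2, or mutant BYL719 replicate 2 or 3 (adjusted p = 0.0521 to 0.0692).

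Of 21 cholesterol genes, 3 fell more in mutant cells, 9 adjusted over the list alone, with HMGCS1 (-0.44) and IDI1 (-0.33) as examples (median -0.18, camera adjusted p = 2.62e-06, adjusted p = 0.039 with an estimated correlation). Of 25 MYC and ribosome genes, 4 fell more, 12 adjusted over the list alone, such as RRS1 (-0.54; median -0.21, camera adjusted p = 2.45e-09, adjusted p = 0.0936 with an estimated correlation). Receptors and adaptors had 5 more positive of 18, such as GAB2 (1.46), and 8 adjusted over the list alone. Their median was 0.27, and 0.17 without mutant DMSO replicate 2 (camera adjusted p = 1.96e-06; adjusted p = 0.399 with an estimated correlation). PI3K components had 3 more positive of 28, and 9 with 1 more negative adjusted over the list alone. Their median was 0.21, and 0.08 without mutant DMSO replicate 2 (camera adjusted p = 3.62e-05; adjusted p = 0.427 with an estimated correlation). Basal markers had 1 more positive of 19, TP63 (0.67), 4 adjusted over the list alone; their median was 0.19, and 0.11 without mutant DMSO replicate 2 (camera adjusted p = 0.00676, adjusted p = 0.427 with an estimated correlation). Matrix genes (median 0.30, camera adjusted p = 0.0144, adjusted p = 0.427 with an estimated correlation) did not pass without mutant DMSO replicate 2 (median 0.14, adjusted p = 0.0864) or mutant BYL719 replicate 3 (adjusted p = 0.191). Cell cycle genes (camera adjusted p = 0.0267, adjusted p = 0.427 with an estimated correlation) did not pass without mutant BYL719 replicate 3 (adjusted p = 0.0808). Lysosome genes (camera adjusted p = 0.0457, adjusted p = 0.427 with an estimated correlation) did not pass without parental DMSO replicate 1, 2 or 3, parental BYL719 replicate 1 or 3, mutant DMSO replicate 1 or 3, or mutant BYL719 replicate 1 or 3 (adjusted p = 0.0539 to 0.326). Fatty acid genes (adjusted p = 0.892) passed without mutant DMSO replicate 2 (adjusted p = 0.0134), and ATF4 targets (adjusted p = 0.102) without mutant BYL719 replicate 1 (adjusted p = 0.0257). ERK output (0.73), NF-kB genes (0.892), p53 targets (0.892) and epithelial markers (0.73) did not pass.

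By edgeR 606 genes had an interaction: 438 were more positive in mutant cells, 168 more negative. Without mutant DMSO replicate 2 there were 1874 (1011 and 863), with 603 of the 606 kept. There were 346, 273 and 243 without parental DMSO replicate 1, 2 or 3, and 239, 254 and 295 without parental BYL719 replicate 1, 2 or 3. There were 301 and 287 without mutant BYL719 replicate 2 or 3; DESeq2 gave 1429 and effective-length offsets 272.

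PDK4, GLUL and HMGCS1 are among the genes that BYL719 moved the same way in both lines. Of the 178 genes that rose in parental cells, 175 also rose in mutant cells (26.9 for independent lists). Of the 124 that fell, 122 also fell (16.3). Fisher's exact test gave p = 2.28e-140 and 2.36e-105, but genes are not independent and the calls share a fit. Across these 302 genes the median ratio of the log2 change in mutant cells to that in parental cells was 2.03 (quartiles 1.5 and 2.55). The number of parental calls also made in mutant cells was 72, 96 and 131 without parental DMSO replicate 1, 2 or 3, 100, 84 and 77 without parental BYL719 replicate 1, 2 or 3, and 1843 without mutant DMSO replicate 2, as the parental count itself moved.

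**Figure D4:**
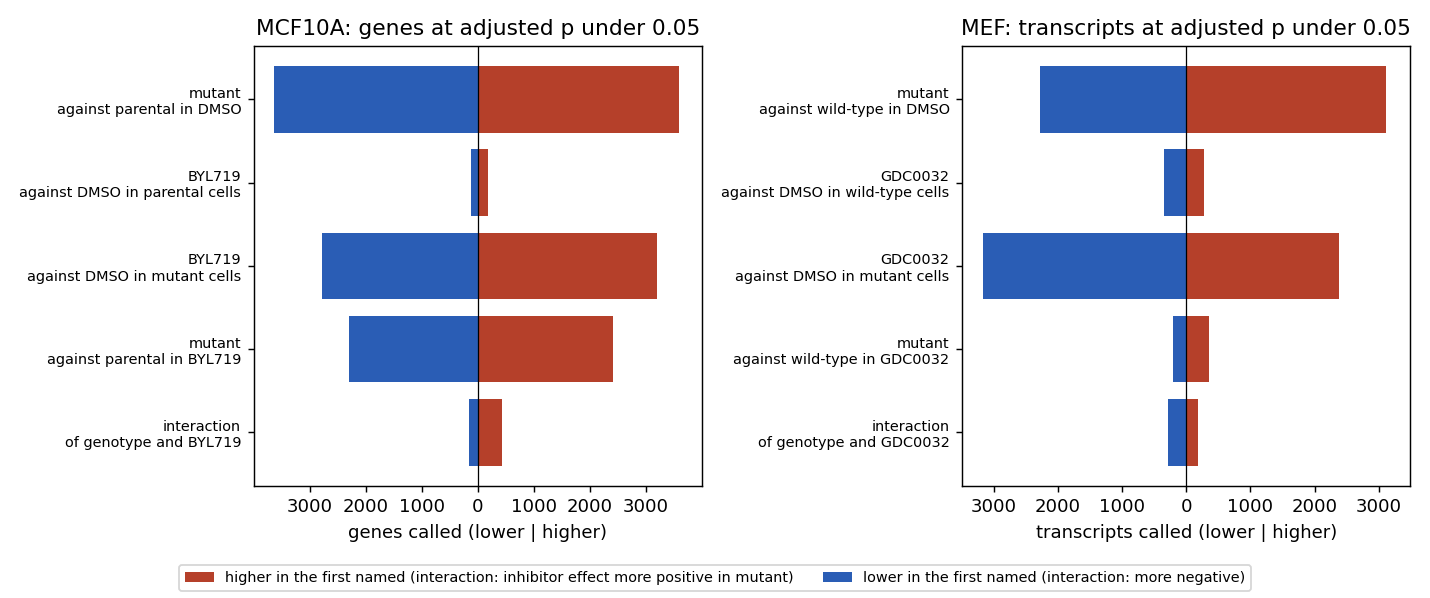
Numbers of genes (MCF10A) or transcripts (MEF) called at adjusted p under 0.05 in the 5 comparisons of each system, with red bars to the right for higher and blue bars to the left for lower in the first-named group; for the interaction, higher means a more positive inhibitor effect in mutant cells. In MCF10A 7213 genes are called between the lines in DMSO, and in MEF 5385 transcripts.

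In MEF, mutant against wild-type cells in DMSO asks which transcripts differ after Cre in place of GFP virus. Transcript ENSMUST00000187103.1 rose from 3.61 ± 0.176 to 9.73 ± 0.393 CPM (log2 1.43, SE 0.119, adjusted p = 9.39e-05) and ENSMUST00000110103.1 from 3.56 ± 1.16 to 12.7 ± 1.81 CPM (log2 1.84, adjusted p = 0.00285). ENSMUST00000087328.3 fell from 151 ± 14.7 to 30.8 ± 0.393 CPM (log2 -2.30, SE 0.0708, adjusted p = 6.95e-07) and ENSMUST00000090746.2 from 10.9 ± 1.35 to 3.58 ± 0.797 CPM (log2 -1.60, SE 0.144, adjusted p = 0.000144). By edgeR 5385 of 55500 transcripts were called, 3110 higher and 2275 lower, 403 and 672 of them by at least 1.5-fold. The count was 3427 and 3432 without wild-type DMSO replicate 1 or 2 and 3500 and 3502 without mutant DMSO replicate 1 or 2; DESeq2 called 8256.

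GDC0032 against DMSO in mutant MEF asks what the inhibitor changes where the mutation is homozygous. It lowered ENSMUST00000187103.1 to 3.13 ± 0.464 CPM (log2 -1.63, adjusted p = 2.71e-05) and ENSMUST00000110103.1 to 4.35 ± 0.869 CPM (log2 -1.55, adjusted p = 0.00597). It raised ENSMUST00000090746.2 to 12.5 ± 0.941 CPM (log2 1.81, adjusted p = 4.36e-05), while ENSMUST00000087328.3 stood at 29.4 ± 0.789 CPM. In all, 5560 transcripts were called, 2382 higher and 3178 lower, 890 and 647 by at least 1.5-fold. In wild-type MEF 635 were called, 280 higher and 355 lower, 41 and 52 by at least 1.5-fold. The wild-type count was 136 and 171 without wild-type DMSO replicate 1 or 2, 269 and 395 without wild-type GDC0032 replicate 1 or 2, 61 when only the wild-type libraries were fitted and 2700 by DESeq2.

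Mutant against wild-type MEF under GDC0032 asks which differences remain. ENSMUST00000087328.3 was still lower in mutant cells (log2 -2.12, adjusted p = 1.49e-06). Here 549 transcripts were called, 346 higher and 203 lower, 59 and 57 by at least 1.5-fold, and 253 (19.4 for independent lists) and 126 (8.32 for independent lists) of the transcripts called in DMSO were called the same way. Over the 5385 transcripts called in DMSO the median ratio of the log2 change under GDC0032 to that in DMSO was 0.32 (quartiles 0.10 and 0.55). The count of 549 fell to 184 without wild-type GDC0032 replicate 2, and to 201, 155 and 271 without mutant GDC0032 replicate 1, 2 or 3; it was 3 when only the 2 groups compared were fitted and 2960 by DESeq2. The number called with both treatments was 144 and 239 without wild-type GDC0032 replicate 2 or 3, and 232 and 210 without wild-type DMSO replicate 1 or 2. It was 235 and 240 without mutant DMSO replicate 2 or 3, and 146, 107 and 196 without mutant GDC0032 replicate 1, 2 or 3.

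ENSMUST00000187103.1, ENSMUST00000110103.1 and ENSMUST00000090746.2 are examples of MEF transcripts whose difference the inhibitor moved back. Of the 3110 transcripts higher in mutant MEF in DMSO, 1856 fell with GDC0032 (178 for independent lists), and of the 2275 lower ones 1239 rose (97.6 for independent lists). At a change of at least 1.5-fold in both comparisons the balance turned round, with 135 and 331. The same 3 mutant DMSO libraries enter both comparisons; the overlap of 0 in simulations without any effect does not measure their part, since 0 or 1 transcripts were called there. The covariance of the fold changes was -0.546, and -0.316 in the simulations (-0.334 to -0.298), and the correlations were -0.495 and -0.501. Part of the excess may come from the shared libraries, which are too few to be divided. The total moved back was 2027 without mutant DMSO replicate 1.

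The MEF interaction asks whether GDC0032 acted differently by genotype, and ENSMUST00000187103.1 fell more in mutant cells (log2 -1.25, adjusted p = 0.012). In total 459 transcripts were called, 174 more positive and 285 more negative in mutant cells. The count was 258 and 168 without wild-type GDC0032 replicate 1 or 2, and 136, 140 and 169 without wild-type DMSO replicate 1, 2 or 3. It was 160, 170 and 234 without mutant DMSO replicate 1, 2 or 3, and 163, 269 and 174 without mutant GDC0032 replicate 1, 2 or 3; DESeq2 gave 2380. Of the 280 transcripts that rose in wild-type MEF 209 also rose in mutant MEF (12 for independent lists). Of the 355 that fell 294 also fell (20.3). Fisher's exact test gave p = 4.69e-224 and 1.37e-303, limited as in MCF10A. The median ratio of the log2 change in mutant to that in wild-type MEF was 1.37 (quartiles 0.78 and 1.84), and 0.71 (quartiles 0.04 and 1.44) over the 93 transcripts changed by at least 1.5-fold in wild-type cells. That overlap was 215 and 299 without wild-type GDC0032 replicate 1 or 2, 124, 144 and 333 without wild-type DMSO replicate 1, 2 or 3, and 332 and 329 without mutant DMSO replicate 1 or 2.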

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

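The tests of copy number, of the pseudoautosomal region, of the ratio of fold changes between treatments, of a swap, and of PI3K output over called genes were chosen after the result was seen; the others were planned.

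The difference between inhibitor effects in the genotypes, tested as an interaction, brought these results here. It called 606 MCF10A genes and 459 MEF transcripts. The effect of BYL719 was more positive in mutant MCF10A cells for CCDC85A (log2 2.24), the transporter SLC7A2 (2.12), the histone gene HIST2H4B (2.01, uncertain because histone copies are nearly identical and lost without the low-count filter, adjusted p = 0.0543) and PIK3CA (0.56, lost with effective-length offsets, adjusted p = 0.0828, and without parental DMSO replicate 2 or 3, parental BYL719 replicate 1 or 2, or mutant BYL719 replicate 2 or 3, adjusted p = 0.0521 to 0.0692). It was more negative for KRT16 (-1.20), the chemokine receptor CXCR5 (-1.19), CDKN1C (-0.97) and the GTPase RHOV (-0.95); CXCR5 lost the call without any 1 parental library, mutant DMSO replicate 2 or 3, or mutant BYL719 replicate 2 or 3 (adjusted p = 0.0582 to 0.128), without the low-count filter (0.206) and with effective-length offsets (0.0809). RHOV lost it without parental DMSO replicate 1 or 3, any 1 parental BYL719 library, or mutant BYL719 replicate 2 (adjusted p = 0.0528 to 0.0661). The median interaction was 0.66 for FOXO targets, 0.27 for receptors and adaptors, 0.21 for PI3K pathway components, -0.18 for cholesterol genes, -0.21 for MYC and ribosome biogenesis, -0.0533 for the cell cycle, 0.30 for matrix genes, 0.0493 for lysosome genes and 0.19 for basal markers. Without mutant DMSO replicate 2 it was 0.17 for receptors and adaptors, 0.08 for PI3K pathway components, 0.14 for matrix genes (adjusted p = 0.0864) and 0.11 for basal markers. FOXO targets and cholesterol genes kept the call with an estimated correlation (adjusted p = 0.00945 and 0.039), and the other lists lost it (adjusted p = 0.0936 to 0.427). The call of lysosome genes was lost without any 1 library other than parental BYL719 replicate 2, mutant DMSO replicate 2 or mutant BYL719 replicate 2 (adjusted p = 0.0539 to 0.326). Without mutant BYL719 replicate 3 the calls of cell cycle and matrix genes were lost (adjusted p = 0.0808 and 0.191).

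With 100 splits of the 12 MCF10A libraries, 4 gave as many calls as the 606 of the real groups, the real one included. All 4 are among the 9 splits that keep the DMSO labels. The 91 splits that exchange DMSO labels put the difference between the lines into the spread (median 0 calls, highest 361), so the splits do not exclude chance regrouping. The highest other split had 7972 calls and exchanges genotype labels under BYL719 but not in DMSO. Such splits hold the difference between the lines, a structure of the samples. With 25 splits drawn in MEF, 3 gave at least the 459 calls of the real groups, the real one included, so chance regrouping is not excluded; both other such splits exchange genotype labels under GDC0032 but not in DMSO, and the highest had 1330 calls. In pairs of groups fitted alone, 10 splits cannot give a share under 0.05, and 1 split, the real one, gave as many calls each time. The real and highest other counts in MCF10A were 5050 and 0 for the mutation in DMSO (edgeR), 3484 and 2 for BYL719 in parental cells, 2610 and 1 for BYL719 in mutant cells, and 6745 and 0 for the mutation under BYL719. In MEF they were 4648 and 1, 61 and 2, 4318 and 0, and 3 and 1.

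The mutant and parental MCF10A lines differ at many genes that were not called for BYL719 in mutant cells. Such genes may still have moved. Copy number over long autosomal runs was argued against as the main cause: runs of 40 neighbouring genes with a median log2 change of at least 0.4 in size held 0.575% of the called autosomal genes (40 of 6954), and in the run with the largest median, -0.62 on chromosome 5, 35 of the 40 genes are protocadherins. Changes of fewer genes or smaller size were not tested. The outlying mutant DMSO library was argued against too, since 8382 genes were called without it. Both tests took all genes called between the lines, including those that BYL719 moved. Reversible PI3K alpha signalling stays open. The median ratio of the difference under BYL719 to that in DMSO was 0.62, and 0.77 over genes changed by at least 1.5-fold in DMSO. It was 0.49, 0.67 and 0.53 without mutant DMSO replicate 1, 2 or 3, so it depends on single libraries. Choosing genes by their call in DMSO also favours a ratio below 1. A treatment of 4 h may be too short for the difference to be undone, and the mutation cannot be told apart from other differences between the lines. Both the mutation and the history of the line remain candidate explanations.

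Genes of pseudoautosomal region 1, at the end of the short arm of chromosome X, were lower in the mutant MCF10A line. Of 16 tested genes, 12 fell and 0 rose, with a median log2 of -0.90 in DMSO (quartiles -1.10 and -0.68) and -0.90 under BYL719, and 18 of 20027 runs of 16 autosomal genes were as low. PI3K alpha signalling that BYL719 reverses within 4 h was argued against, because BYL719 changed the genes by a median of -0.0157 in mutant cells; a slower effect of the mutation stays open. The upper quartile of the 22 tested genes in the neighbouring 10 Mb was 0.12, where a loss of all of that stretch was taken to lower them together. That test cannot decide, because losing an X copy from which a gene is not expressed leaves its level unchanged. Of those 22 genes 9 fell and 5 rose, 16 were below 0 and the median was -0.48 in DMSO (-0.09 under BYL719). A loss that reaches part or all of that stretch stays open. Loss of a copy of the region in the mutant line is consistent with the median of -0.90 and is a hypothesis, since it was found and tested on the same data.

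Mutant DMSO replicate 2 stands apart from the other mutant DMSO MCF10A libraries. Its deviation followed gene length (Spearman rho -0.36 across 20985 genes, which are not independent replicates; rho 0.17 with GC content), with a median of 0.21 in the genes of the shortest length class and -0.24 in those of the longest, with 4 classes of nearly equal size, so a length-related difference in RNA or library is a candidate explanation; long transcripts such as FAT1 and UTRN were lower and short ones such as RPL41 and UQCR11 higher. Replicate 2 had a negative rho with length in each of the 4 MCF10A groups (-0.0952, -0.0982, -0.3561 and -0.1548). A swap with an inhibitor-treated library was argued against: over 1323 genes that BYL719 changed by at least 1.5-fold in mutant cells without that library, its deviation divided by that change had a median of -0.0101 (quartiles -0.3082 and 0.2973), where a swap needs about 1. The test of a swap planned before, the r of 0.0474 with the BYL719 effect in parental cells, did not decide. Stronger PI3K output in that culture stays open. Its deviation had r 0.0474 (Spearman -0.0877) with the BYL719 effect in parental cells, where a value above -0.1 was planned to count against it. A shift smaller than that of the inhibitor need not pass that limit, since even the BYL719 effects in mutant and parental cells had an r of 0.2090 across all genes. Over the 302 genes called for BYL719 in parental cells the deviation had r -0.2745, and -0.1109 with the length trend removed, which does not decide. Of the 178 raised genes 124 were lower in that library (95 with the length trend removed), and 62 of the 124 lowered genes were higher. Its total of 131117011 pairs lay within the range of the others.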

How the results depend on the processing

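The fits of single transcripts in MCF10A, and those without mutant DMSO replicate 2 in comparisons that do not use it, were chosen after the data were seen; the other alternatives were planned. Counts are of called MCF10A genes or MEF transcripts, and for each value the cause was not tested unless given. Named genes and transcripts were not followed under the test against a 1.5-fold change or in the fits of single MCF10A transcripts. Of 181 results for named MCF10A genes, 134 kept their direction and side of the threshold under every other alternative that tested them. Of the rest, 46 lost the call under at least 1, and 0 reversed. For 76 results for named MEF transcripts the numbers were 29, 47 and 0. The planned overlap with MEF genes and the MEF lists were not run, as MEF identifiers could not be paired with genes. In simulated data edgeR recovered 53.1%, 68% and 96% of MCF10A genes changed by 1.5, 2 and 4 fold, and 17.8%, 27.1% and 54.2% of MEF transcripts, and 6.38% and 0% of the calls were of unchanged ones, so fewer changes can be seen in MEF; its depth, its spread and testing by transcript were not separated.

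DESeq2 gave 891 for BYL719 in parental cells and 1429 for the MCF10A interaction (56.9% more positive, against 72.3%), and 860 parental calls also made in mutant cells. In MEF it gave 8256 for the mutation in DMSO, 2700 for GDC0032 in wild type, 2960 for the mutation under GDC0032, 2380 for the interaction, 4664 moved back, 1692 called with both treatments and 1749 called in both genotypes. Effective-length offsets gave 134 in parental cells, 131 shared with mutant cells and 272 for the interaction (84.2% more positive). Testing against a 1.5-fold change (glmTreat of edgeR), a stricter question by construction, gave 1265, 7, 350, 1064 and 37 for the mutation in DMSO, BYL719 in parental and mutant cells, the mutation under BYL719 and the interaction. In MEF the same order gave 16, 1, 98, 6 and 5.

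With only the 2 groups compared the counts were 3484 in parental cells (48.0% higher, against 58.9%), 2610 in mutant cells, 1409 moved back and 1726 in both genotypes, and in MEF 61 for GDC0032 in wild type, 3 for the mutation under GDC0032, 2 with both treatments and 48 in both genotypes. Without the low-count filter, which tests more transcripts, MEF gave 401, 357 and 205 for GDC0032 in wild type, the mutation under GDC0032 and the interaction, 249 with both treatments and 327 in both genotypes. With a mean of at least 5 CPM, which tests fewer, these were 1415, 1254, 978 (51.7% more positive, against 37.9%), 837 and 1050. Single MCF10A transcripts gave 4568, 25, 3327, 2664 and 70 in the order of the comparisons.

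With group means subtracted, same-numbered libraries correlated at -0.07 to 0.08 in MCF10A and -0.03 to 0.03 in MEF, too low to pair them. Yet so measured, 10 of 12 MCF10A libraries were closest, among those of other groups, to a same-numbered one (4 by chance). This hint is not from the design. In MEF it was 3 of 12. A replicate block moved no MCF10A count by over 1.5 times and gave, in MEF, 261 for GDC0032 in wild type, 193 for the mutation under GDC0032, 116 for the interaction, 151 with both treatments and 231 in both genotypes.

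Restricted to changes of at least 1.5-fold, which removes smaller ones, 600 MCF10A genes moved back (175 that were higher in mutant cells and 425 lower, in place of 1555 and 1611), 1596 were called with both treatments (625 higher and 971 lower) and 59 in both genotypes (48 up and 11 down, 81.4% up in place of 58.9%). In MEF these were 466 (135 higher and 331 lower, which turns round the balance of 1856 and 1239), 30 (17 and 13) and 42 (21 up and 21 down). With an estimated correlation 5, 3, 3, 5 and 2 lists were called in place of 15, 11, 11, 14 and 9, and fry called 6 in parental cells.

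Leaving out 1 library gave 73 to 1973 in parental cells, 72 to 1843 of them also in mutant cells, 3562 to 7442 for the mutation under BYL719 and 239 to 1874 for the MCF10A interaction; 1973, 7442, 1843 and 1874 are without mutant DMSO replicate 2. In MEF it gave 3427 to 3930 for the mutation in DMSO, 136 to 590 for GDC0032 in wild type, 155 to 441 for the mutation under GDC0032, 136 to 308 for the interaction, 2027 to 2560 moved back, 107 to 306 with both treatments and 124 to 444 in both genotypes. The balance of rises and falls also moved across 50%. The share that rose was 50.1% to 52.4% in place of 49.6% for the mutation in DMSO (RLE, DESeq2, at least 5 CPM, or without mutant DMSO replicate 1, 2 or 3). Under BYL719 it was 42.0% to 49.9% in place of 51.2% (these settings other than the left-out libraries, no low-count filter, effective-length offsets, glmTreat, single transcripts, or without any 1 parental BYL719 library or mutant BYL719 replicate 1 or 3). For BYL719 in parental cells it was 49.0% by DESeq2, and for genes called in both genotypes 46.0% to 48.8% in place of 58.9% (DESeq2, or without mutant DMSO replicate 2 or mutant BYL719 replicate 1). For genes moved back it was 50.1% to 55.6% in place of 49.1% (RLE, DESeq2, at least 5 CPM, or without parental DMSO replicate 1 or 2, any 1 mutant DMSO library or mutant BYL719 replicate 1). With at least 5 CPM MEF gave 48.9%, 50.1% and 49.5% for the mutation in DMSO, GDC0032 in mutant cells and transcripts moved back, in place of 57.8%, 42.8% and 60.0%. The counts for the mutation in DMSO (5759 to 8382) and BYL719 in mutant MCF10A cells (4237 to 6977), and GDC0032 in mutant MEF (3728 to 4241), stayed within 1.5 times.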

Other observations

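The tests of length trends in each comparison were chosen after the result was seen. Markers of cells other than mammary epithelium were fixed as lists to look for RNA of other sources. In mutant against parental MCF10A cells in DMSO, 2 of 7 tested haematopoietic markers rose and 1 fell (camera adjusted p = 0.345): the lysosomal membrane gene LAPTM5 rose (log2 2.21) and the receptor gene CSF1R fell (-0.75). Of 9 endothelial markers 3 rose and 1 fell (adjusted p = 0.832), with ESAM up (0.98; adjusted p = 0.0627 without parental DMSO replicate 2, 0.0617 without mutant DMSO replicate 1 and 0.06 when only the 2 groups compared were fitted) and the transcription factor gene ERG down (-2.74). Of 8 adipocyte markers 2 rose and 3 fell (adjusted p = 0.452, median 0.02, or -0.04 without mutant DMSO replicate 2, and mean -0.89), with the fatty acid transporter CD36 down (-1.13). Of 6 neural and glial markers 1 rose and 2 fell (adjusted p = 0.517), with NES, an intermediate filament of progenitor cells, down (-1.01) and SOX2 down (-1.17). Of 4 skeletal muscle markers DES rose (1.55; adjusted p = 0.575 with effective-length offsets and 0.0559 without parental DMSO replicate 1), and the list was not tested.

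With BYL719, the adjusted p values of camera in parental cells were 0.587 for haematopoietic, 0.207 for endothelial, 0.0803 for adipocyte and 0.583 for neural markers, and in mutant cells 0.707, 0.267, 0.763 and 0.485. In mutant cells 1 of 7 haematopoietic markers rose and 2 fell, 2 of 9 endothelial markers rose, 1 of 8 adipocyte markers rose (CD36, log2 1.69) and 1 fell (PPARG, -0.21), and 1 of 6 neural markers rose (MAP2, 1.03) and 3 fell (SOX2 the most, -1.01). The PPARG call was lost without the low-count filter, with a replicate block, when only the 2 groups compared were fitted, and without mutant DMSO replicate 1 or mutant BYL719 replicate 2 or 3 (adjusted p = 0.0603 to 0.155). The SOX2 call was lost when only the 2 groups compared were fitted and without mutant DMSO replicate 2 or mutant BYL719 replicate 3 (adjusted p = 0.0509 to 0.107). Under BYL719 the comparison of mutant with parental cells gave 0.196 for haematopoietic, 0.754 for endothelial, 0.0719 for adipocyte and 0.183 for neural markers, and the interaction gave 0.961, 0.533, 0.269 and 0.234.

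The fold changes of MCF10A genes followed gene length where mutant DMSO libraries were compared. Spearman's rho across genes was -0.10 for the mutation in DMSO, 0.14 for BYL719 in mutant cells and 0.17 for the interaction, and 0.02, 0.01 and 0.01 without mutant DMSO replicate 2; genes are not independent replicates. The fold changes with and without that library had correlations of 0.949, 0.885 and 0.901 across genes.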
